A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

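Mutation rates of yeast rRNA were taken from one deposited table with a column for each of the 8 libraries. Per the labels' protocols, purified ribosomes were incubated with drug, treated with DMS and quenched, and the rRNA was fragmented with zinc chloride and size-selected. A linker was ligated, cDNA was made with the thermostable group II intron reverse transcriptase TGIRT-III, and full-length products were circularised and amplified. Because full-length products were kept, methylation is read as mismatches and not as stops. The submitters' processing notes name cutadapt, Bowtie2 and the genome build sacCer3, without versions or roles, and the filters, base-quality limits and minimum depth are not given in the sources used here. The values deposited are a fraction per nucleotide, from 0 upward, and are printed here as percentages. PCR copies were not removed by any step that the labels record. The fraction carries no read depth, so neither counting intervals nor weights by depth were used, and the precision of low rates cannot be stated. The 21 nucleotides listed at 0 in every library all lay within 4 nucleotides of an rRNA end.

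Each library was assigned to its condition by its title. Rates were tested for A and C nucleotides with a mean rate of at least 0.5% over the 7 DMS libraries, which left 514 of 5475 nucleotides. Values were analysed as log2(rate + 0.001), with each library's median over the tested nucleotides subtracted. The constant added shrinks the change at low rates, so the fold changes on this scale understate it there. With 1 library per condition, a nucleotide was called in a drug library when its log2 ratio had a size of at least 1 with the same sign against both the DMSO and the no-addition library, and no p-value was given. As a secondary test, limma 3.58.1 (lmFit, eBayes with a trend, R 4.3.3) was fitted to the 7 DMS libraries in 3 classes, without drug (2 libraries), AglA (2) and CHX (3), with 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The labels do not say whether libraries came from separate ribosome preparations. The comparisons of AglA and of CHX against no drug share the same control libraries, and no overlap between them is reported. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

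The limma step was tested on simulated data for the 514 nucleotides, with 20 nucleotides lowered by each of 0.5, 1 and 2 on the log2 scale. In the AglA comparison 14, 19 and 20 of these were recovered, with 2 of 454 unchanged nucleotides called, and in the CHX comparison 19, 19 and 20, with 5 of 454. The simulated noise was drawn independently for each nucleotide and library. It held no DMSO or dose difference shared by many nucleotides, so these figures do not give the error rate of limma in the real libraries.

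The nucleotides named in the text followed a rule fixed before the data were examined. It took every tested member of the structural lists, up to 10 lower and 10 higher nucleotides per drug by the 2-fold rule at the highest dose with the same sign at every dose, and the 10 largest called by limma in each direction. Nucleotides outside that rule, among them A971, A929, A1132, A1133, C2078, C3350, C2942, 5.8S A155 and those of the closing section outside the tested set, were chosen after their values were seen, as was the bound that gave the list of 12 nucleotides that differ with DMSO. The lists were the CHX pocket of the E site, the peptidyl transferase centre, the A loop, the sarcin-ricin loop, helix 69, the decoding centre, bases modified on the base-pairing edge, and other modified bases. Their positions were listed from memory, without a structure or published map at hand. Each listed nucleotide was checked against the base in the table, which does not show that the position belongs to the named site, and 2 that differed were dropped, since the table has G92 where the E site list had a C, and U2822 where the peptidyl transferase list had an A. A list's median was compared with 10000 random lists of the same size matched on mean rate, as a description of these libraries.

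Positions in rRNA were converted to the first annotated gene copies on chromosome XII in the R64 assembly, which sacCer3 also denotes. These are RDN25-1 (451786 to 455181), RDN18-1 (455933 to 457732), RDN58-1 (455414 to 455571) and RDN5-1 (459676 to 459796), whose lengths equal those in the table. The strand of the 25S gene was taken from its locus tag, and the genome sequence was not used here. The deposited rates do not separate the rDNA copies.

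The alternatives tried were added constants of 0.0001 and 0.01, no filter or a filter at 2% on the mean rate, no centring, subtraction of the rate without DMS, each control library alone, a 1.5-fold rule, eBayes without trend, and leaving out each DMS library in turn. Fits of limma against single control libraries, fits without nucleotides of at least 0.5% in the library without DMS, and the nearest library without drug before centring, were chosen after seeing the data.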

Results

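Purified 80S ribosomes of the yeast *Saccharomyces cerevisiae* were incubated with a drug in vitro and then probed with dimethyl sulfate (DMS), to locate where the drug sits on the ribosomal RNA (rRNA). DMS methylates the base-pairing edge of adenosine and cytidine where neither a base pair nor a bound molecule covers it. A reverse transcriptase that reads through the methylated base leaves a mismatch in the cDNA, so the mutation rate of a nucleotide is the share of reads with a mismatch there. A drug that covers a reactive base lowers its rate. There were 8 libraries, 1 per condition. They comprised ribosomes without DMS, ribosomes with 90 mM DMS and no addition, and ribosomes with DMS and the solvent dimethyl sulfoxide (DMSO). The others had DMS and agelastatin A (AglA), an alkaloid of marine sponges, at 0.5 or 1.0 mM, or DMS and cycloheximide (CHX), an inhibitor of translation elongation that binds the exit (E) site of the large subunit, at 10, 50 or 1000 µM. DMS acted for 8 min. Rates were given for 5475 nucleotides, of which 3396 are in 25S, 1800 in 18S, 158 in 5.8S and 121 in 5S rRNA. Read depth is unknown, so no counting interval is given for any rate. With 1 library per condition, differences between libraries have no replicate check.

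Adding DMS raised mutation rates mostly at adenosines and at a part of the cytidines. The median rate of the 1453 adenosines was 0.0360% without DMS and 0.188% with DMS and no addition, and 456 of them were at least 10-fold higher with DMS. The 1076 cytidines had medians of 0.0594% and 0.0939%, and 116 were at least 10-fold higher. Fewer guanosines and uridines, 19 of 1495 and 15 of 1451, were at least 10-fold higher. The median log2 ratio of the 2 libraries, with 0.1 percentage points added to each rate, was 1.02 for A, 0.18 for C, 0.33 for G and 0.13 for U. This size depends on the constant added, and for A it was 2.05 with 0.0001 and 0.18 with 0.01 added to the rate as a fraction.

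Nucleotides that yeast itself methylates on the base-pairing edge gave high rates without DMS, which places the numbering of the deposited table. The m1A nucleotides A645 and A2142 of 25S rRNA had rates of 87.6% and 56.1% in the library without DMS, and 87.0% and 56% with DMS and no addition. The m3U nucleotides U2634 and U2843 of 25S had 83.5% and 82.9% without DMS, and U1191 of 18S, a hypermodified pseudouridine, had 82.8%. The adjacent dimethyladenosines of 18S differed from each other, with 0.558% at A1781 and 11.0% at A1782. Of the other modified bases listed, 18S C1773 had 1.04%, 18S C1280 had 0.674%, 18S G1575 had 0.574%, and 25S C2870 and C2278 had 0.0646% and 0.0566%.

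All comparisons with drugs used the 514 A and C nucleotides (381 A and 133 C) whose mean rate over the 7 DMS libraries was at least 0.5%. They comprised 292 nucleotides of 25S, 199 of 18S, 15 of 5.8S and 8 of 5S rRNA. Their median rate was 0.0544% without DMS, 1.74% with no addition and 1.66% with DMSO. It was 1.58% and 1.60% with 0.5 and 1.0 mM AglA, and 1.31%, 1.52% and 1.44% with 10, 50 and 1000 µM CHX. On the log2 scale the median over these nucleotides lay below that of the DMSO library by at most 0.06 with AglA (-0.06 and -0.05), and at -0.32, -0.12 and -0.20 with CHX. Log2 ratios below are relative to each library's own median, with 0.001 added to each rate.

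A small group of reactive nucleotides, most of them in 18S rRNA, differed between the DMSO and the no-addition library. Of the 514 nucleotides, 2 differed by at least 2-fold between the DMSO and the no-addition library, and both were lower with DMSO. C439 of 25S had 11.4% with no addition and 4.93% with DMSO (log2 ratio -1.13), and A971 of 18S had 2.78% and 1.28% (-1.0). At a size of at least 0.5 on the log2 scale, a bound chosen after the values were seen, 12 nucleotides differed. Of these, 10 were lower with DMSO, namely 7 in 18S (A929, A971, A1131, A1132, A1133, A1655 and A1746) and 3 in 25S (C439, A847 and A2049), while C2078 and C3350 of 25S were higher. The standard deviation of the log2 ratio over all 514 nucleotides was 0.19, and 95% of the ratios were within 0.36 of 0. After centring, both AglA libraries were nearer the DMSO library and all 3 CHX libraries nearer the no-addition library at all 12 nucleotides. Without centring, tried after the values were seen, the 0.5 and 1.0 mM AglA libraries were nearer DMSO at 11 and 12 of them, and the 10, 50 and 1000 µM CHX libraries nearer no addition at 6, 12 and 12. The count past 2-fold rests on A971 lying at the threshold, and it was 1 with 0.01 added to the rate. With 0.0001 added it was 3, with A847 also lower. After subtraction of the rate without DMS it was 2, with C439 lower and C969 of 25S higher, a base at 2.10% without DMS.

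**Figure D1:**
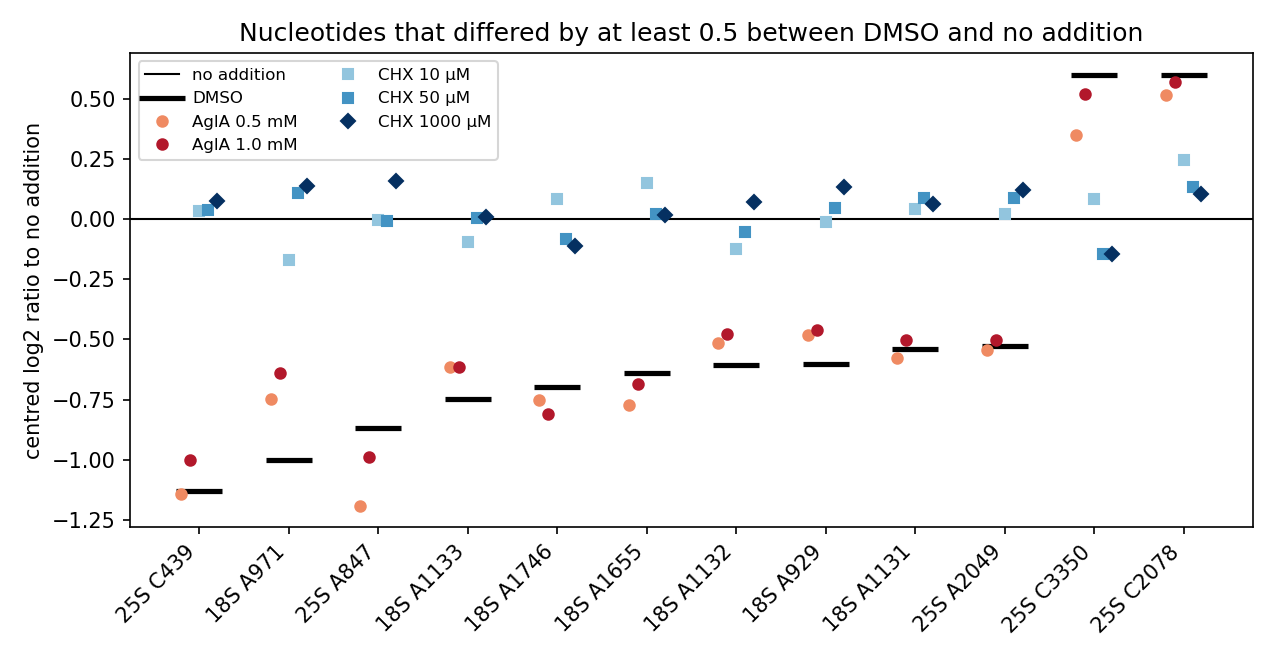
Centred log2 ratio to the no-addition library (vertical axis) at the 12 nucleotides that differed by at least 0.5 between the DMSO and no-addition libraries, 1 library per symbol. Thick bars are the DMSO library, circles the 2 AglA libraries and squares and diamonds the 3 CHX libraries; at C439 the DMSO library lies at -1.13, with both AglA libraries near it and the CHX libraries near 0.

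With AglA, C2821 of 25S rRNA lost nearly all of its reactivity. C2821 lies in the peptidyl transferase centre, where the ribosome forms peptide bonds. Its mutation rate was 5.68% with no addition and 5.87% with DMSO, but 0.180% with 0.5 mM and 0.221% with 1.0 mM AglA, against 0.0921% without DMS. The DMSO rate was 32.5 and 26.6 times the rate at the lower and the higher AglA dose, and the log2 ratios to DMSO were -4.35 and -4.17. In each AglA library C2821 was the 1 nucleotide that differed at least 2-fold from both the DMSO and the no-addition library, and 0 were higher by that rule. C2821 corresponds to position 452361 of chromosome XII on the minus strand (genome build sacCer3, R64), in RDN25-1, the first annotated copy of the 25S gene, which spans 451786 to 455181. It is the centre of the rRNA sequence ACAGGGAUAACUGGCUUGUGG. Because the rDNA is repeated, this position stands for all copies.

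**Figure D2:**
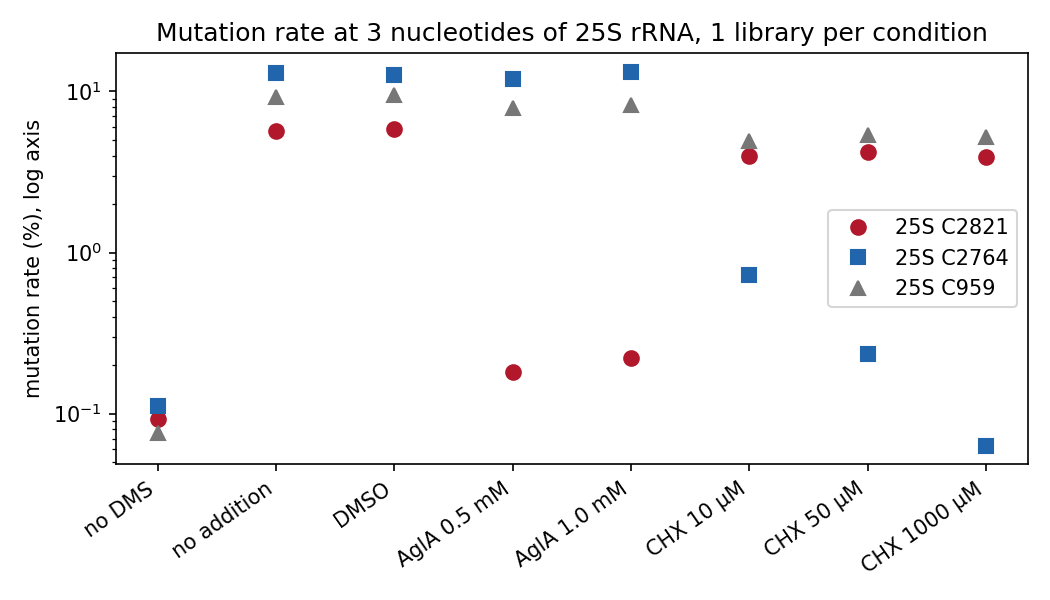
Mutation rate in percent on a log axis for 25S C2821 (circles), C2764 (squares) and C959 (triangles) in the 8 libraries, 1 library per condition and so without error bars. C2821 is at 0.180% and 0.221% in the AglA libraries and at 3.92% or more in the other DMS libraries, and C2764 is at 0.724%, 0.234% and 0.0633% in the CHX libraries and at 12.0% or more in the other DMS libraries.

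As a set, the other tested nucleotides were close to the DMSO library with AglA. Without C2821 and C2764, the standard deviation of the log2 ratio to DMSO was 0.11 and 0.13 at the 2 AglA doses, and that to the no-addition library was 0.21 at both. The nucleotides next in size below DMSO, named after their values were seen, were 25S C2942 at 0.5 mM (-0.62) and 5.8S A155 at 1.0 mM (-0.78). In limma, with both AglA doses as one class and both libraries without drug as another, C2821 fell by 4.20 on the log2 scale (standard error 0.083, adjusted p = 3.19e-10, lower in 2 of 2 AglA libraries). It was 1 of 514 nucleotides to pass, with 0 higher, and 59 had an unadjusted p under 0.05. Doses are not replicates, and the class without drug holds the DMSO difference, so the p-value measures the spread among these single libraries. The count was 80 (30 lower and 50 higher) when the DMSO library was left out, and C2821 stayed at -4.29 to -4.11 whichever library was left out. With 0.01 added to the rate it was at -2.44.

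Among the tested members of the structural groups, listed from memory before the data were examined, C2821 was the 1 that limma called with AglA. In the peptidyl transferase centre 6 nucleotides were tested (A2401, A2402, A2404, C2821, A2872 and A2971), and limma called 1 of them, C2821, adjusted over the list alone and over all nucleotides. The median log2 ratio of the group to DMSO was 0.13 at 0.5 mM, at percentile 99.8 of 10000 random groups matched on rate, and 0.02 at 1.0 mM, at percentile 77.8. Without centring these medians were 0.061 and -0.030. Other groups also lay far out at 0.5 mM, with bases modified on the base-pairing edge at percentile 97.9 and helix 69 at 1.96. A2402 had 1.39% with DMSO and 1.63% and 1.44% with AglA, and A2404 had 7.93%, 8.71% and 8.04%. In the CHX binding pocket of the E site, C2764 was the 1 nucleotide tested and had 12.0% and 13.3% with AglA against 12.7% with DMSO. No member of the A loop (1 tested), the sarcin-ricin loop that elongation factors contact (3), helix 69 between the subunits (1), the decoding centre of 18S (3), or the 2 groups of natural modifications (4 and 2) was called by limma, adjusted over the list alone or over all nucleotides. Their median log2 ratios to DMSO at 0.5 and 1.0 mM were 0.01 and 0.08 for the A loop, -0.09 and -0.11 for the sarcin-ricin loop, -0.20 and -0.14 for helix 69, and -0.05 and -0.07 for the decoding centre. They were 0.10 and 0.06 for bases modified on the base-pairing edge, and -0.03 and 0.11 for other modified bases.

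With CHX a different nucleotide lost its reactivity, C2764 of 25S rRNA, in the pocket of the E site where CHX is known to bind. Its rate was 12.9% with no addition and 12.7% with DMSO. With CHX it was 0.724% at 10 µM, 0.234% at 50 µM and 0.0633% at 1000 µM, the last below the 0.112% of the library without DMS. The DMSO rate was 17.6 and 54.5 times that at 10 and 50 µM, and the log2 ratios to DMSO at the 3 doses were -3.64, -5.14 and -6.10. The last depends on the constant added, with -3.56 for 0.01 and -7.23 for 0.0001. In each CHX library C2764 was the 1 nucleotide that differed at least 2-fold from both libraries without drug. C2764 corresponds to position 452418 of chromosome XII on the minus strand in RDN25-1, and is the centre of the rRNA sequence GCCUAUCGAUCCUUUAGUCCC.

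A second cytidine of 25S, C959, was lower by a smaller amount at every CHX dose. It had 9.21% with no addition and 9.48% with DMSO, and 4.91%, 5.36% and 5.20% with 10, 50 and 1000 µM CHX, against 7.94% and 8.27% with AglA. C959 corresponds to position 454223 of chromosome XII in RDN25-1, within CGAAGUUUCCCUCAGGAUAGC. In limma, with the 3 CHX doses as one class, C2764 fell by 4.94 on the log2 scale (standard error 0.52, adjusted p = 0.000901) and C959 fell by 0.60 (standard error 0.056, adjusted p = 0.000567), each lower in 3 of 3 CHX libraries. The standard error at C2764 holds its differences between doses, so these adjusted p-values do not rank C2764 and C959. A2398 and A2142 of 25S were higher by 0.41 (standard error 0.067, adjusted p = 0.0220) and 0.25 (standard error 0.043, adjusted p = 0.0220), on values centred on the library medians and in 3 of 3 libraries. A2398 had 2.69% with no addition and 2.38% with DMSO against 2.65%, 2.86% and 3.04% with CHX, and it had 3.07% and 3.15% with AglA, where the rise was 0.37 (adjusted p = 0.0917). A2142 is one of the m1A nucleotides, with 56.1% without DMS. It had 56% and 54.5% without drug against 52.8%, 57.3% and 57.0% with CHX, and the 10 µM rate was below both. Without centring its difference was 0.011, against 0.16 for A2398, so the call at A2142 came from centring. Without centring neither was called (adjusted p = 0.121 and 0.824) and limma called 255 nucleotides lower and 0 higher with CHX, in place of 2 and 2. The count of 4 became 86 without the no-addition library, and 2 (C2764 and C959) without the DMSO library or without either AglA library, and A2398 was also lost without the 10 or 1000 µM library and A2142 without the 1000 µM library.

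**Figure D3:**
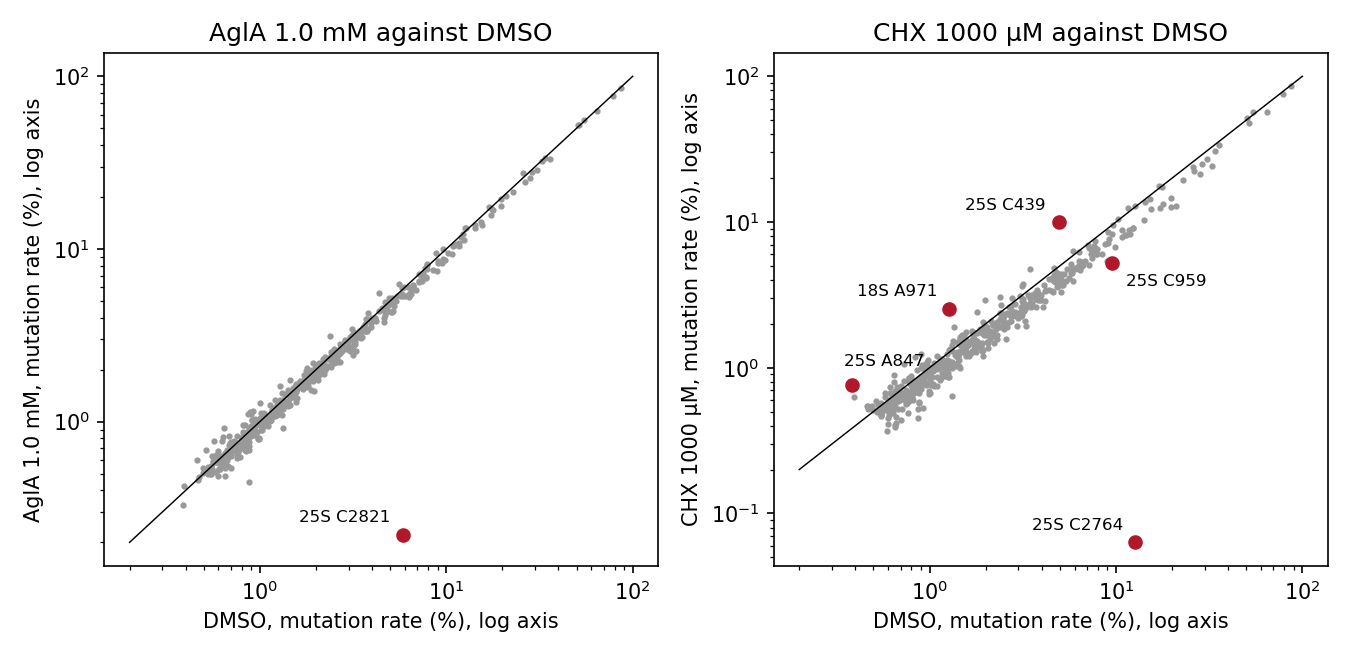
Mutation rate in percent of the 514 tested nucleotides in the 1.0 mM AglA library (left) and the 1000 µM CHX library (right) against the DMSO library, on log axes, with the line of equal rates. C2821 at 0.221% and C2764 at 0.0633% lie far below the line, and C439, A971, A847 and C959 are marked on the right.

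Away from C2764, the CHX libraries were closer to the no-addition library than to the DMSO library. Without C2821 and C2764, the standard deviation of the log2 ratio was 0.22, 0.22 and 0.23 against DMSO and 0.14, 0.12 and 0.14 against no addition. Against DMSO alone, the 2-fold rule added C439 at 10 µM, C439 and A971 at 50 µM, and C439, A971 and A847 at 1000 µM, all higher with CHX. C439 had 8.94%, 10.3% and 9.99% with CHX, near the 11.4% of the no-addition library. The solvent of CHX is not given in the labels. limma against a single control library, a fit added after the data were seen, had 1 library on that side. Its spread came from the drug doses alone, so only differences are given here. C959 was at -0.66 against DMSO and -0.55 against no addition, and C2764 at -4.96 and -4.92.

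By structural group, C2764 was the 1 tested nucleotide of the E site list and passed both over the list alone and over all nucleotides. U2763, G2793 and G2794 of that list are not A or C and were not tested. In the peptidyl transferase centre, C2821 had 3.99%, 4.23% and 3.92% with CHX against 5.87% with DMSO, and it was called lower adjusted over the list alone (1 of 6) but not over all nucleotides (log2 difference -0.26, adjusted p = 0.137), where it passed without the no-addition library (-0.31). The median log2 ratio of this group to DMSO was 0.06, -0.14 and -0.07 at 10, 50 and 1000 µM. Without centring it was -0.25 at 10 µM and -0.27 at 1000 µM. Of the 4 tested bases modified on the base-pairing edge, 3 (A645, A2142 and A1782) were called higher adjusted over the list alone and 1 (A2142) over all nucleotides. Of the 2 other modified bases 1 (C1773) was called higher over the list alone and 0 over all. Among all 514 tested nucleotides, 87 had an unadjusted limma p under 0.05 with CHX, so calls over a list alone do not set a group apart. Before centring, the rates of A645 were 86.1% to 86.6% with CHX against 87.0% with no addition, and without centring its difference changed sign. Without centring the differences fell from 0.37 to 0.13 at A1782, from 0.25 to 0.011 at A2142 and from 0.25 to 0.0092 at C1773. The rates of C1773 were 0.886%, 0.989% and 1.05% with CHX against 1.03% with no addition. No tested member of the A loop, sarcin-ricin loop, helix 69 or decoding centre was called by limma. Their median log2 ratios to DMSO at 10, 50 and 1000 µM were -0.09, -0.17 and -0.10 for the A loop, -0.05, -0.11 and -0.09 for the sarcin-ricin loop, 0.08, 0.01 and 0.09 for helix 69, and 0.18, 0.04 and 0.12 for the decoding centre.

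Compared directly, the drugs protected different cytidines. At the same molar dose, C2821 had 0.221% with 1.0 mM AglA and 3.92% with 1000 µM CHX, while C2764 had 13.3% and 0.0633%. In limma, AglA minus CHX was -3.94 at C2821 (standard error 0.076, adjusted p = 2.46e-10) and 5.0 at C2764 (standard error 0.52, adjusted p = 0.000809). C959 was higher with AglA by 0.49 (standard error 0.056, adjusted p = 0.00122). In all, 37 nucleotides were lower and 24 higher with AglA than with CHX. Of the 59 other than C2821 and C2764, 53 had the same sign as the difference between the DMSO and the no-addition library. No such share was worked out for the nucleotides not called, so this count does not set the called ones apart. The largest of those lower with AglA were 25S A847 (-1.14), C439 (-1.12), A2049 (-0.60) and A2547 (-0.55) and 18S A1655 (-0.79), A1746 (-0.75), A1671 (-0.61), A1131 (-0.61) and A1003 (-0.58), with adjusted p from 0.0171 to 0.0252. Those higher with AglA were led by 18S A1005 (0.58), A65 (0.43) and A1707 (0.39) and 25S C482 (0.55), C1846 (0.51), A213 (0.43), A848 (0.42) and C1219 (0.40). The nucleotides listed here as lower and higher also differed in that direction between the DMSO and the no-addition library. Those differences were -1.13 (C439) to -0.19 (A2547) for the lower ones and 0.20 (C1219) to 0.45 (C1846) for the higher ones. These calls therefore cannot be assigned to either drug.

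By structural group, AglA minus CHX was called at 4 of the 6 tested nucleotides of the peptidyl transferase centre adjusted over the list alone, with C2821 and A2971 lower and A2402 and A2404 higher with AglA, and at 2 over all nucleotides, C2821 and A2402 (0.31, adjusted p = 0.0423). C2764 of the E site, A2256 of helix 69 (-0.23, adjusted p = 0.0496) and A1755 of the decoding centre (-0.31, adjusted p = 0.0317) passed both ways. C2925 of the A loop was called higher with AglA over the list alone (1 of 1, which is its unadjusted limma p of 0.040) and not over all. In this comparison 178 of the 514 tested nucleotides had an unadjusted limma p under 0.05. Calls over a list alone therefore do not by themselves set a group apart. Of the 4 bases modified on the base-pairing edge, 3 were called lower with AglA over the list alone and 1, A1782 (-0.34, adjusted p = 0.0304), over all, and none of the sarcin-ricin loop or of the other modified bases was called by limma. Without centring A2256, A1755 and A1782 were not called over all nucleotides, and A645 and A2142 changed sign. The count of 61 changed with the libraries used. It was 3 (C2821, C2764 and C959) without the 10 µM CHX library, 10 without the 50 µM and 32 without the 1000 µM CHX library. Leaving out an AglA library or a library without drug leaves 1 in its class, so no count is given here. The libraries without drug do not enter this difference, so leaving 1 out changed only the estimate of spread. The differences themselves moved less when any library was left out, at -1.24 to -1.04 for A847 and -1.19 to -1.05 for C439. Without centring, 14 nucleotides were lower and 171 higher with AglA.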

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

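The rule that selected the nucleotides in this part was chosen after the values were seen, and other bounds had been looked at before. The tests on these nucleotides were also chosen after the values were seen, except limma with no filter on the rate, which was fixed beforehand. Outside the tested set, 702 nucleotides (416 A or C and 286 G or U) had a mean rate of at least 0.2% over the DMS libraries. Among them, 7 differed from both libraries without drug, in the same direction at every dose of a drug, by more than 0.36 on the centred log2 scale. That bound is the 95th percentile of the size of the DMSO to no-addition difference in this set. No chance rate was estimated for this count. The values given are the smallest log2 ratio over doses and controls.

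With AglA, 4 of these nucleotides moved. A2820 of 25S, the next nucleotide before C2821, was lower (-0.51), with 0.337% in the no-addition library and 0.274% in the DMSO library against 0.152% and 0.149% with AglA. A2941 of 25S was also lower (-0.46), with 0.340% and 0.219% against 0.122% and 0.116%. U2875 of 25S, in the peptidyl transferase list, was higher (0.48), with 0.304% and 0.336% against 0.481% and 0.525%. A288 of 18S was higher (0.37), with 0.219% and 0.235% against 0.313% and 0.340%. When limma was run with no filter on the rate, it called A2820 (-0.71, adjusted p = 0.00174), A2941 (-0.80, adjusted p = 0.00174) and C2942 (-0.55, adjusted p = 0.0262) lower with AglA, along with C2821. In that run each library was centred on the median of all A and C nucleotides, which lowered the AglA differences. C2821 went from -4.20 to -4.31 and A2401 from 0.13 to 0.020, so a part of these falls came from centring.

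These shifts in both AglA libraries were weighed against random variation and the solvent. The solvent stays open, because A2820 and A2941, at -0.46 or lower against the DMSO library, were selected for a difference from that library and so cannot test it. Random variation stays open too. Over 8 members of the list without C2821, the median size of the shift was 0.14 against 0.078 in random lists. This lay at percentile 97.5, between the bounds set for either reading. These members include A2820, U2875 and U2954 from outside the tested set. A2820 and U2875 were selected for their shifts, so the percentile cannot decide the question. Read depth, which sets the error of rates this low, is unknown. Local rearrangement of these bases by bound AglA is a candidate explanation that was not tested.

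With CHX, A2762 of 25S, 2 nucleotides before C2764, was higher (0.57), with 0.293% and 0.357% without drug against 0.479%, 0.521% and 0.528%. C1787 of 18S (0.38) and G1018 of 25S (0.38) were also higher in every CHX library after centring. Without centring the smallest log2 ratios were 0.34 for A2762, 0.14 for C1787 and 0.12 for G1018, all under the bound, as was A288 with AglA (0.30). C1787 had 0.200% without DMS against 0.214% with DMS and no addition. C1787 and G1018 had higher rates with AglA than with DMSO as well, at 0.280% and 0.293% against 0.221% for C1787, and 0.229% and 0.276% against 0.188% for G1018.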

How the results depend on the processing

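The fold rule gave C2821 for AglA and C2764 for CHX under every alternative run, and limma kept both past its threshold under every alternative and with any library left out. With a library left out C2821 was at -4.29 to -4.11 and C2764 at -5.60 to -4.37, and over the other alternatives they were at -4.72 to -2.44 and -5.51 to -3.24, closest to 0 with 0.01 added. The other counts moved, and the causes were not tested beyond what the alternatives themselves change. Fits to single control libraries and without natural signal were chosen after seeing the data. With 1 control library, in these fits or with the other left out, the spread came from the drug doses alone. Those counts therefore give no error rate. By the 2-fold rule, subtracting the rate without DMS gave 2 nucleotides for 0.5 mM AglA (adding A2142), 2 for 10 µM CHX (adding A1782), 3 for 50 µM (adding both) and 2 for 1000 µM (adding A2142), at bases whose signal without DMS is large. Against DMSO alone the CHX counts were 2, 3 and 4, against no addition alone the 0.5 mM AglA count was 3 (adding C439 and A847), and a 1.5-fold rule gave 2 at 50 µM CHX (adding C959). DMSO against no addition gave 1 in place of 2 with 0.01 added or without natural signal, 3 with 0.0001 added, and 10 by the 1.5-fold rule. After subtraction of the rate without DMS it stayed at 2, but with C969, higher with DMSO, in place of A971. In limma, AglA against no drug gave 4 nucleotides with no filter, 2 with no centring (adding C2942) and 79 against no addition alone, in place of 1. CHX against no drug gave 16 with 0.01 added, 44 with no filter, 14 with the filter at 2%, 255 with no centring, 86 against DMSO alone and 2 against no addition alone, in place of 4. AglA against CHX gave 185 with no centring and 38 after subtraction of the rate without DMS, in place of 61. Leaving out each library gave 1 to 80, 2 to 86 and 3 to 146 nucleotides in these comparisons.

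The log2 ratio of the E site list (C2764) to DMSO was -2.79, -3.40 and -3.56 at 10, 50 and 1000 µM CHX with 0.01 added, -5.58 and -7.23 at 50 and 1000 µM with 0.0001 added, -3.96 and -6.30 at 10 and 1000 µM with no centring, and -3.86, -5.74 and -6.84 after subtraction of the rate without DMS. The peptidyl transferase list was at -0.25 and -0.27 at 10 and 1000 µM with no centring. The median log2 ratio with DMS over without was 2.05 for A and 0.69 for G with 0.0001 added, 0.18 and 0.056 with 0.01 added, and 3.53 for A, 3.67 for C and 2.20 for G over nucleotides of at least 0.5%.

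Of 1239 alternative values at named nucleotides, 1019 kept their direction and side of the threshold, 112 lost the call, 34 gained one and 74 changed sign. The 1019 include values at nucleotides not called to begin with, which could not lose a call. They therefore do not measure how firm the calls were. The sign changes were all at nucleotides not called over all nucleotides in that comparison. Of these, A645 (CHX against no drug, and AglA against CHX) and A2142 (AglA against CHX) had been called adjusted over the list alone, and they changed sign with no centring. For AglA against no drug these were, with no filter, C2764 -0.049, A2872 -0.0082, C2925 -0.0014, A3029 -0.079, A645 -0.033, A1782 -0.083, C1280 -0.083 and C1773 -0.052, with no centring C2764 -0.027, A3029 -0.056, A645 -0.010, A1782 -0.060, C1280 -0.060 and C1773 -0.029, against DMSO alone A3029 -0.066 and C1280 -0.027, and against no addition alone C1274 0.038. For CHX against no drug they were, with no filter, A2401 -0.098, A2872 -0.14, A2971 -0.12, A3029 -0.17, A2256 -0.079, A1755 -0.034, A1756 -0.15, A1781 -0.094 and C1280 -0.031, with no centring A2401 -0.13, A2872 -0.17, A2971 -0.16, A3029 -0.21, A2256 -0.11, A1755 -0.071, A1756 -0.18, A645 -0.011, A1781 -0.13 and C1280 -0.068, after subtraction of the rate without DMS A1781 -0.30, with 0.01 added C2925 0.0055, against DMSO alone A3029 -0.065, and against no addition alone C2925 0.0098 and C1274 0.00015. For AglA against CHX they were, with no filter, A3021 0.068, A3027 0.059 and A3029 0.095, with the filter at 2% A2401 -0.032 and C1274 -0.016, with no centring A3021 0.13, A3027 0.12, A3029 0.15, A1756 0.00083, A645 0.00028, A2142 0.012 and C1280 0.0077, and A3029 0.0095 with 0.0001 added, 0.0040 after subtraction and 0.0016 without natural signal, with A3027 0.0021 with 0.01 added. With each library left out, values that changed sign ranged for AglA from -0.066 to 0.13 (A3029), -0.027 to 0.082 (C1280), -0.15 to 0.038 (C1274), -0.050 to 0.11 (A1782), -0.0058 to 0.13 (C2764) and -0.037 to 0.15 (C1773), for CHX from -0.065 to 0.13 (A3029), -0.12 to 0.0098 (C2925) and -0.19 to 0.00015 (C1274), and for AglA against CHX from -0.038 to 0.11 (A2872), -0.037 to 0.036 (A3029) and -0.054 to 0.00093 (A3021). Unknown read depth limits every low rate, above all the CHX rates of C2764.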

Other observations

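The tests in this part were all chosen after the values were seen, and the hypotheses were found in the same data.

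At U2634 of 25S, an m3U nucleotide, the rate was 83.5% without DMS and 63.5% to 66.7% in the 7 DMS libraries. The other highly mutated natural modifications had no such gap, with A645 at 86.0% to 87.0% and U1191 at 80.4% to 83.1% in the DMS libraries. With CHX, U2843 of 25S had 77.0% to 78.7% against 82.6% to 83.8% in the 5 other libraries, and U1191 of 18S had 80.4% to 81.7% against 82.8% to 83.1%.

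The AglA libraries resembled the DMSO library and the CHX libraries the no-addition library at the nucleotides where those libraries without drug differed. Regressed on the DMSO to no-addition difference over 512 nucleotides, the distance from the midpoint of those libraries had slopes of 0.43 and 0.39 for AglA and -0.38, -0.44 and -0.47 for CHX, where 0.5 is the DMSO library itself and -0.5 the no-addition library. The extent of the DMS reaction is argued against, since the CHX libraries had the lowest median rates and would then have lain on the DMSO side, whereas their largest slope was -0.379. The same slopes are what DMSO present with AglA and absent with CHX would give, so solvent is a candidate explanation that the labels do not settle. A preparation batch cannot be told apart from it, because the no-addition library was nearer the CHX mean at 3 of 11 natural modification sites, between the bounds set for either reading.

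C959 of 25S was lower in all 3 CHX libraries. Presence or absence of DMSO is argued against, since the CHX libraries lay at -0.52 or lower against the no-addition library too. At C959 the DMSO library differed from the no-addition library by 0.10 on the centred log2 scale. The extent of the DMS reaction was set against 22 cytidines with comparable rates, of which 0% had a lower mean CHX ratio. The lowest of them, C2531, was at -0.14 against -0.55 for C959. C959 was singled out as called lower among all 514 nucleotides. Its rank was thus largely fixed beforehand, and the extent of the reaction stays open. A CHX solvent other than DMSO was not tested, as no library holds one without CHX, and a batch of the CHX libraries cannot be excluded, because at 3 of 11 natural modification sites all CHX libraries lay on one side of all 5 others, where chance gives 3.57% per site. An effect of bound CHX on C959 therefore remains a hypothesis.

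The protection of C2764 by dose was set against a model with 1 CHX site of fixed affinity and free drug equal to total drug. With the 1000 µM library as the floor, 5.17% of the signal was left at 10 µM, which predicts 1.08% at 50 µM, and 1.33% was observed, a ratio of 1.24 of observed over predicted. With the library without DMS as the floor the residuals were 4.81% at 10 µM and 0.959% at 50 µM, a ratio of 0.958. These values may reflect a single site with an apparent half-dose of 0.546 µM (0.506 µM with the other floor). Either half-dose is extrapolated to below the lowest dose used, 10 µM. The rates were not centred here, and the median of the 10 µM library lay at -0.32 against DMSO on the log2 scale. Each dose has 1 library, and the ribosome concentration is not given in the labels. For AglA no dose series could be read at C2821. It had 0.180% at 0.5 mM and 0.221% at 1.0 mM, both already near the 0.0921% of the library without DMS.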
